A study of Mus musculus with 6 samples.

How the data were processed

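Single cells of the hepatic bilio-vascular tree, the portal tissue that holds the bile ducts and vessels, were measured by droplet RNA sequencing in 6 libraries of wild-type C57BL/6 mice. 3 libraries came from sham-operated mice and 3 from mice after bile duct ligation (BDL). Per the labels, BDL livers were perfused with more collagenase and loaded at a higher target of cells than sham livers, and dead cells were removed. The labels put BDL replicate 3 alone in a second sequencing batch and give no duration of BDL. Nothing in the labels pairs a sham mouse with a BDL mouse, so the groups were compared unpaired.

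The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 7.0.0 on the mm10 (GRCm38) genome. The header of the BDL replicate 3 matrix names Cell Ranger 8.0.1. The submitters' notes also name bcl2fastq 2.20 and R 4.1.3. All other deposited columns (unit "other" in the record of the files) are barcodes and gene names. The feature list holds 55357 gene IDs, of which 52081 were found in a GRCm38 gene annotation used for positions. All values below were computed from the counts.

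Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Scrublet scores were computed with scanpy 1.11.5 on 30 principal components in each library, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes. This left 46176 of 52527 barcodes, 15470 from sham and 30706 from BDL, with 3907 removed as doublets. Counts were scaled to 10000 per cell and logged for clustering only, with 3000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9), without integration of libraries. Each of 46 clusters was named from marker lists. A name needed 3 detected markers, each with a UMI in at least 25% of the cluster's cells and a fold of at least 2, and classes carry the suffix "-like" for that reason. 277 cells of 1 cluster stayed unnamed. Mesenchymal cells were clustered again in each batch with 2000 variable genes, 30 components and resolution 0.5. This left out the matrix, contractile, TGF-beta response, proliferation, KLF family and dissociation and immediate-early lists, and genes that correlated above 0.15 with proliferation. Matrix degradation, chemokine and cytokine, interferon response, quiescence and adventitial genes were not left out, so they could shape the sub-clusters. The first clustering left out only mitochondrial and ribosomal genes. They were split into fibroblast-like, HSC-like (hepatic stellate cell) and smooth muscle/pericyte-like cells. Fibroblast-like cells were further split into a Clec3b/Pi16-type and other cells.

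Cells are not replicates, so UMIs were summed per library and class, with at least 10 cells per sum and at least 2 sums per group. Sums were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Errors of log2 fold changes are standard errors from that fit, and errors of means are SDs over 3 libraries. CPM is taken from class sums after TMM. Percents of the level in another class, whole-library values, ratios of counts, bounds and the free RNA estimate of Klf4 use CPM before TMM. Sums of 2 classes of the same mice were compared with library as a block. The difference between the BDL responses of fibroblast-like and HSC-like cells was tested as an interaction. 24 gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01 and again with an estimated correlation, and their members were counted over all genes and adjusted over the list alone. Shares were compared with two-sided exact permutation tests, which for 3 against 3 libraries cannot give a p below 0.1. Intervals of count ratios are 95% Clopper-Pearson intervals and, like the floor of 3 counts over a group that stands in for a group without a UMI, they cover counting error only.

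The named genes follow a rule fixed before the data were examined, as were the groups, tests, lists and alternatives. It takes 11 fixed genes, the 6 largest rises and 6 largest falls with adjusted p under 0.05, a mean CPM of at least 20 and no overlap between groups, and up to 4 members with the smallest p of each list described. Predicted, mitochondrial, ribosomal, immunoglobulin and haemoglobin genes and a fixed list of acute phase and hepatocyte genes were left out of the largest changes. That list does not hold Lcn2. In comparisons within BDL, marker genes other than the fixed genes were not named, but counts of list members include them. Which lists to describe in which class was chosen after the list results were seen. A gene named outside the rule is said to be so.

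The tests were checked on simulated data in which 200 genes of the real sums were changed. In fibroblast-like sums 84.8% of genes changed 4-fold and 8.96% of genes changed 1.5-fold were called, with 7.37% false calls. In cholangiocyte-like sums these were 89.4%, 26.9% and 7.69%. The interaction recovered 40.9% of genes changed 4-fold, with 8.11% false calls, and the class term within BDL 83.3%, with 10.1% false calls. For the interaction and the class term, no mouse effect shared by the classes was simulated, although the real tests take library as a block. The 200 changed genes are also far fewer than were called in most real comparisons. These rates may therefore not carry over to the real tests. A raised list was called, and 0 of 20 random lists were. Genes were drawn independently of each other, so this could not test how correlated genes affect the list test.

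Alternatives changed 1 choice at a time, and a library whose sum then fell under 10 cells was left out as well. They were DESeq2 (1.42.0) size factors and its Wald test, no filter, a mean CPM of at least 20, batch or replicate number as a term, no block, leaving out each library, doublets kept, at most 10% mitochondrial UMIs, at least 800 genes and 1500 UMIs, equal cell numbers, clustering resolutions 0.5 and 2, and sub-clustering resolution 1. Neutrophil-like cells were too few in sham to be tested. Other software was Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.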

Results

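The series asks how bile duct ligation (BDL), surgical closure of the common bile duct that causes cholestasis and portal scarring, changes the cells of the mouse bilio-vascular tree. Its title names Clec3b-positive fibroblasts, the transcription factor KLF4 and periostin. 3 sham and 3 BDL libraries were measured. Sham libraries held 60751535, 73298819 and 41447935 UMIs in 6075, 7374 and 5043 barcodes, and BDL libraries 144093179, 141855403 and 119966209 in 11173, 11665 and 11197 barcodes. After filtering, 5623, 6787 and 3060 sham cells and 10160, 10541 and 10005 BDL cells stayed, with medians of 8546, 7537 and 10440 UMIs per sham cell and 10514, 10111 and 8991 per BDL cell. The median mitochondrial share of these cells was 2.53%, 2.5% and 2.30% in sham and 0.912%, 0.905% and 2.07% in BDL. Of 10 mitochondrial genes, 3 fell in fibroblast-like, 4 in HSC-like, 5 in cholangiocyte-like, 3 in endothelial-like and 2 in monocyte/macrophage-like cells, and 0 rose (camera adjusted p = 0.00825, 0.00338, 0.0236, 0.0122 and 0.0387; 0.656, 0.438, 0.487, 0.448 and 0.519 with an estimated correlation). In sham replicate 3, 1797 barcodes were under the gene and UMI minimum. BDL replicate 3 differed more from the other BDL libraries than these did from each other. Chi-square per degree of freedom was 32.7 between BDL replicates 1 and 2, and 331 and 301 between each of them and replicate 3.

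Fibroblast-like, monocyte/macrophage-like and neutrophil-like cells made up more of the captured cells after BDL, and endothelial-like cells less. Fibroblast-like cells were 2.03% ± 0.376 (SD, n = 3) of sham and 13.9% ± 2.60 of BDL cells. HSC-like cells, the vitamin A-storing pericytes of the sinusoid, were 1.64% ± 0.115 and 7.05% ± 0.330. Monocyte/macrophage-like cells were 3.84% ± 0.433 and 29.5% ± 2.80, neutrophil-like cells 0.0760% ± 0.0119 and 2.64% ± 0.660, and T/NK-like cells 1.95% ± 0.678 and 7.07% ± 1.77. Endothelial-like cells were 58.2% ± 2.77 and 5.64% ± 0.358, Kupffer-like cells (resident liver macrophages) 2.45% ± 0.453 and 1.09% ± 0.130, and B cell-like cells 1.15% ± 0.703 and 0.338% ± 0.0665. In each of these 8 named classes no BDL library overlapped a sham library, and the two-sided exact permutation p was 0.1, the smallest possible (adjusted p = 0.15 over 15 classes), so none passed. Chance gives groups without overlap in 10% of cases. Groups overlapped for cholangiocyte-like cells (19.8% and 20.9%, exact permutation p = 0.6), dendritic-like cells (4.44% and 6.25%, p = 0.3) and smooth muscle/pericyte-like cells (1.07% and 1.12%, p = 0.8). Unnamed cells were 0.845% and 0.451%, and unnamed mesenchymal cells 0.370% and 3.19%. In batch 1 alone (without BDL replicate 3) the differences, BDL minus sham, were 13.3 points for fibroblast-like, 5.33 for HSC-like, 27.2 for monocyte/macrophage-like and -52.6 for endothelial-like cells, and -0.573 for cholangiocyte-like and -0.235 for smooth muscle/pericyte-like cells, against 1.14 and 0.0494 over all libraries. These are shares of captured cells, and BDL livers were perfused with more collagenase and loaded at a higher target of cells.

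**Figure D1:**
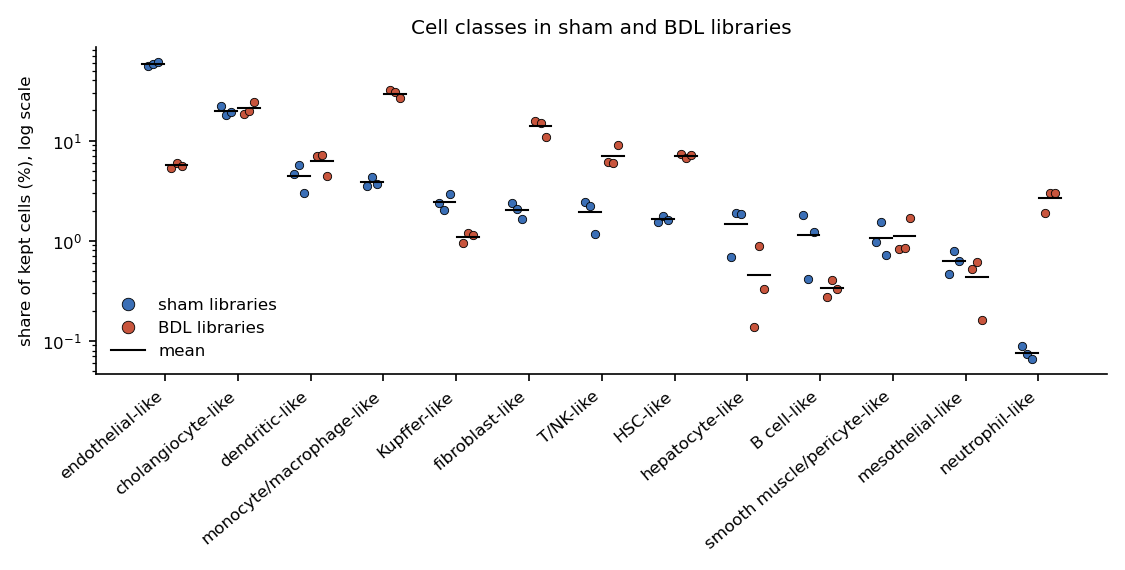
Share of captured cells (percent, log axis) in each cell class, with 1 point per library and a bar at the group mean for sham and BDL. Endothelial-like cells go from a mean of 58.2% in sham to 5.64% in BDL, and fibroblast-like cells from 2.03% to 13.9%.

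The captured transcripts of the fibrillar collagens Col1a1, Col1a2 and Col3a1, the main proteins of scar tissue, lay mostly in fibroblast-like cells in both groups. They were 0.0480%, 0.0615% and 0.0467% of all UMIs in the sham libraries and 0.777%, 0.741% and 0.753% in the BDL libraries. Fibroblast-like cells held 67.3% ± 3.20 (SD, n = 3) of them in sham and 62.8% ± 7.34 in BDL (two-sided exact permutation p = 0.5). HSC-like cells held 15.9% ± 1.24 in sham and 25.9% ± 0.880 in BDL, without overlap (exact permutation p = 0.1, adjusted p = 0.188). Per cell, fibroblast-like cells went from 189 to 393 collagen UMIs and HSC-like cells from 53.1 to 318. The shares of collagen UMIs depend on how many cells of each class were captured, in BDL 13.9% fibroblast-like and 7.05% HSC-like cells. In BDL replicate 3, unnamed mesenchymal cells held 16.3% of the collagen UMIs, against 1.89% and 1.76% in BDL replicates 1 and 2. With doublets kept, the share of fibroblast-like cells in BDL was 47.9%.

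The 11 genes fixed in advance are given here by gene ID and position on GRCm38, all protein-coding. Clec3b (ENSMUSG00000025784), which encodes the secreted C-type lectin tetranectin, lies on chromosome 9 from 123150946 to 123157432. Klf4 (ENSMUSG00000003032), a zinc-finger transcription factor, lies on chromosome 4 from 55527143 to 55532466. Postn (ENSMUSG00000027750), which encodes the matricellular protein periostin, lies on chromosome 3 from 54361109 to 54391037. The collagens are Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) and Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706). Acta2, smooth muscle actin, is ENSMUSG00000035783 (chromosome 19, 34241090 to 34255590). Timp1, an inhibitor of matrix-degrading proteases, is ENSMUSG00000001131 (chromosome X, 20870166 to 20874735). Tgfb1, a fibrogenic growth factor, is ENSMUSG00000002603 (chromosome 7, 25687002 to 25705077). The platelet-derived growth factor receptors are Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215) and Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061).

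In fibroblast-like cells, Postn rose and Clec3b fell after BDL, while Klf4 did not pass the test. Postn went from 64.2 ± 24.8 to 268 ± 79.5 CPM (SD, n = 3 each), a log2 fold change of 2.07 ± 0.30 (SE; edgeR quasi-likelihood adjusted p = 0.00117). Clec3b went from 712 ± 112 to 55.9 ± 5.60 CPM (log2 -3.67 ± 0.17, adjusted p = 3.56e-06). Klf4 was 818 ± 188 CPM in sham and 717 ± 376 in BDL (log2 -0.19 ± 0.32, adjusted p = 0.694), and it was called lower without BDL replicate 3 (log2 -0.74), as with batch as a covariate (-0.72). Col1a1 rose by 1.17 ± 0.20, Acta2 by 2.12 ± 0.36, Timp1 by 3.10 ± 0.33, Tgfb1 by 1.94 ± 0.18 and Pdgfrb by 0.79 ± 0.16 on the log2 scale, and Pdgfra was at -0.36 ± 0.19 (adjusted p = 0.192). In batch 1 alone Postn was at 1.80, Clec3b at -3.77 and Col1a1 at 0.96. In all, 3477 of 13949 genes changed by the edgeR test, 1796 up and 1681 down. Different sub-clusters hold the class in each group: in batch 1, sub-cluster 4 held 315 sham and 23 BDL cells, sub-cluster 8 held 3 and 224, sub-cluster 0 held 2 and 1820 and sub-cluster 1 held 4 and 1111, and in batch 2 sub-clusters 0, 2 and 7 held 574, 419 and 98 BDL cells. The Clec3b/Pi16-type made up 98.5% of the class in sham and 8.17% in BDL (21.6% and 4.84% at sub-clustering resolution 1), so the changes in the class do not tell a change within cells from a change in which cells it holds.

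Among the largest rises in fibroblast-like cells were those of Wfdc18 (1 UMI in sham; ratio of counts 307, 95% interval 55.0 to 12118; in BDL at 2.79% of its level in cholangiocyte-like cells, with Clu at 2.84%, Lcn2 at 3.52% and Spp1 at 8.98%), Igfbp2, an insulin-like growth factor binding protein (log2 6.59 ± 0.74), Col11a1 (5.73 ± 0.87), Kif26b (5.70 ± 0.50) and Piezo2, a mechanically gated ion channel (5.68 ± 0.31). Without sham replicate 2 the fitted values were 12.82 for Wfdc18 and 12.90 for Kif26b, since few or no sham UMIs then remained. The largest falls were of Angptl1 (-6.68 ± 0.71), Cnmd, an inhibitor of vessel growth (-5.55 ± 0.43), Penk, which encodes proenkephalin (-5.09 ± 0.22), Inmt (-4.91 ± 0.29), Vit (-4.83 ± 0.50) and Myoc (-4.77 ± 0.57).

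Of 36 matrix genes tested in fibroblast-like cells, 23 rose and 3 fell, and 25 rose and 4 fell when adjusted over the list alone. Col8a1 rose by 3.13 ± 0.24, Sparc by 1.85 ± 0.20 and Col5a2 by 1.81 ± 0.20 on the log2 scale. The list was called up by camera (adjusted p = 8.00e-06; adjusted p = 0.297 with an estimated correlation). Of 17 contractile genes 9 rose and 1 fell (12 and 1 adjusted over the list alone), with Tpm1 at 1.78 ± 0.15, Actn1 at 1.22 ± 0.15 and the smooth muscle actin Actg2 at 4.31 ± 0.35 (camera adjusted p = 7.19e-04; adjusted p = 0.517 with an estimated correlation). Of 20 TGF-beta response genes 7 rose and 4 fell (8 and 4 adjusted over the list alone). Cthrc1 rose by 3.01 ± 0.26 and Ltbp2 by 2.03 ± 0.25, and Bambi, a decoy receptor of the pathway, fell by 1.10 on the log2 scale. The median of that list was -0.05, its mean 0.36, and camera did not call it (adjusted p = 0.626).

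Genes of adventitial fibroblasts, the quiescent cells of vessel sheaths, fell in fibroblast-like cells: 10 of 16 fell and 1 rose, with the same counts adjusted over the list alone. Gsn, an actin-severing protein, went from 9286 ± 580 to 1546 ± 138 CPM, and Tnxb from 540 ± 55.7 to 88.6 ± 21.5 (camera adjusted p = 3.34e-04; adjusted p = 0.517 with an estimated correlation). The list holds markers by which the class was named. Of 26 chemokine and cytokine genes 11 rose and 5 fell, adjusted over the list alone too. Cxcl14 rose by 3.16 ± 0.20 and Cx3cl1, the anchored chemokine fractalkine, by 1.64 ± 0.14, and Cxcl10 fell by 2.55 (camera adjusted p = 0.0894). Of 20 interferon response genes 10 fell and 0 rose, and 12 fell when adjusted over the list alone. Xaf1 fell by 0.83 (0.61 without sham replicate 2, no longer called) and Usp18 by 1.22 (1.00 without sham replicate 1, no longer called; camera adjusted p = 1.51e-04; adjusted p = 0.517 with an estimated correlation). In the KLF family 1 of 12 genes rose, Klf5 (2.08 ± 0.35), and 4 fell, also adjusted over the list alone, among them Klf9 (-1.10 ± 0.21) and Klf15 (-1.27 ± 0.21), with a camera adjusted p of 0.579. Of 26 dissociation and immediate-early genes 3 rose and 5 fell (3 and 6 adjusted over the list alone), with Ier3 up by 1.06 ± 0.16 and Egr1 down (-0.94 ± 0.15).

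Genes of other cell types moved in fibroblast-like sums too. Of 21 genes of liver sinusoidal endothelial cells (LSEC) 16 fell and 0 rose (17 fell and 1 rose adjusted over the list alone), with Dnase1l3 at -4.74 ± 0.57 and Gpr182 at -3.77 ± 0.40 (camera adjusted p = 1.70e-07; adjusted p = 0.297 with an estimated correlation). Of 14 inflammatory monocyte genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with Il1b at 2.56 ± 0.49 and Ccl3 at 3.53 ± 0.61. Their median was 2.44, or 2.32 with the gene without a sham UMI at its bound (camera adjusted p = 2.37e-04; adjusted p = 0.231 with an estimated correlation). The sums rest on 134, 140 and 50 sham and 1600, 1578 and 1091 BDL cells. The count of changed genes was 1929 without sham replicate 2, 5032 in batch 1 alone (without BDL replicate 3), 5607 with batch as a covariate, 1811 with equal cell numbers and 2096 at a mean CPM of at least 20.

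In HSC-like cells, collagens and Timp1 rose and genes of the quiescent stellate cell fell. Col1a1 went from 1237 ± 84.2 to 7048 ± 1653 CPM (SD, n = 3 each; log2 2.51 ± 0.20, edgeR adjusted p = 3.14e-05), and Timp1 from 13.6 ± 5.24 to 937 ± 250 (6.06 ± 0.31, adjusted p = 1.07e-05). Acta2 rose by 3.24 ± 0.45 and Tgfb1 by 1.35 ± 0.16, and Clec3b fell from a low level of 19.4 ± 6.98 CPM (-2.45 ± 0.44). Klf4 rose from 248 ± 37.8 to 489 ± 183 CPM (0.98 ± 0.25, adjusted p = 0.0159). That call ended without sham replicate 1 (1.09), 2 (0.89) or 3 (1.06), and the value was 0.59 in batch 1 alone, still called, and 0.64 with batch as a covariate. Postn was 325 ± 78.0 and 447 ± 33.2 CPM (0.47 ± 0.19, adjusted p = 0.0943). It passed with the replicate block (0.49), with batch as a covariate (0.44) and without a filter (0.60), over a range of 0.31 to 0.60 for all alternatives. In batch 1 alone Col1a1 was at 2.25 and Timp1 at 6.18. Of 12492 genes 3806 changed, 2038 up and 1768 down. Different sub-clusters hold this class in each group too: in batch 1, sub-cluster 5 held 251 sham and 3 BDL cells, sub-cluster 2 held 2 and 1087 and sub-cluster 3 held 3 and 351, and in batch 2 sub-clusters 1, 4 and 6 held 430, 158 and 134 BDL cells.

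Among the largest rises in HSC-like cells were those of Il6, the inflammatory cytokine (ratio of counts 320, 95% interval 57.5 to 12656), Aldh1a2, an enzyme of retinoic acid synthesis (ratio of counts 271, 95% interval 48.6 to 10714), Gda (ratio of counts 172, 95% interval 30.9 to 6808), Wfdc18 (ratio of counts 151, 95% interval 27.1 to 5966; in BDL at 2.72% of its level in cholangiocyte-like cells, with Clu at 2.69%, Lcn2 at 3.38% and Spp1 at 11.7%) and Ace, the angiotensin-converting enzyme (ratio of counts 173, 95% interval 47.9 to 1430). Each of these had at most 2 sham UMIs, and the call of Wfdc18 ended without sham replicate 2 (11.67). The largest falls were of Hhip, an inhibitor of hedgehog signalling (-6.85 ± 0.36), Ptprt (-6.25 ± 0.70), Angptl6 (-5.46 ± 0.44), Fcna (-5.23 ± 0.44), Tlcd4 (-4.55 ± 0.28) and Bmp10, which acts on endothelium (-4.46 ± 0.42).

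Of 36 matrix genes in HSC-like cells 27 rose and 1 fell (29 and 2 adjusted over the list alone), with the collagen cross-linking enzyme Lox at 3.69 ± 0.26 and Col15a1 at 2.94 ± 0.19 (camera adjusted p = 2.20e-11; adjusted p = 0.0951 with an estimated correlation). Of 16 contractile genes 11 rose and 0 fell, adjusted over the list alone too, with Tpm1 at 2.14 ± 0.16 (camera adjusted p = 8.81e-05; adjusted p = 0.322 with an estimated correlation). Of 19 TGF-beta response genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), with Cthrc1 at 4.65 ± 0.37 and Tgfb3 at 2.10 ± 0.18 (camera adjusted p = 0.0162; adjusted p = 0.225 with an estimated correlation). Of 18 quiescence genes 16 fell and 1 rose, adjusted over the list alone too. Vipr1 fell by 3.73, Ecm1, which restrains TGF-beta activation, by 3.24, and Nr1h4, the bile acid receptor FXR, by 2.87 on the log2 scale (camera adjusted p = 3.16e-09; adjusted p = 0.313 with an estimated correlation). Of 25 chemokine and cytokine genes 17 rose and 1 fell, adjusted over the list alone too, with the neutrophil chemokine Cxcl2 at 4.13 ± 0.45 and Cxcl12 at -2.00 ± 0.18 (camera adjusted p = 6.32e-05; adjusted p = 0.0951 with an estimated correlation). Genes of other cell types moved here too: of 12 inflammatory monocyte genes 11 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 3.34e-06; adjusted p = 0.0951 with an estimated correlation), and of 16 lipid-associated macrophage genes 11 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 4.39e-04; adjusted p = 0.154 with an estimated correlation). In BDL, Cxcl2 was at 5.21% of its level in monocyte/macrophage-like cells, with Lyz2 at 2.02%, Il1b at 1.89% and Ccl3 at 2.01%.

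Of 19 interferon response genes in HSC-like cells 8 fell and 0 rose (10 fell adjusted over the list alone), with Xaf1 at -1.70 ± 0.24 (camera adjusted p = 8.81e-05; adjusted p = 0.438 with an estimated correlation). Of 26 dissociation and immediate-early genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.128), with Ier3 at 1.74 ± 0.21 and Nfkbia at 1.07 ± 0.18. LSEC genes fell here as well, 10 of 20, with 0 rising and the same counts adjusted over the list alone, and Clec4g at -2.13 ± 0.24 (camera adjusted p = 4.02e-05; adjusted p = 0.313 with an estimated correlation). Of that list, Rspo3 and Fcna were at 1026 and 841 CPM in HSC-like sham cells, against 34.3 for Clec4g and 28.8 for Dnase1l3. Falls of the first pair need not be those of another cell type. The sums rest on 87, 120 and 49 sham and 738, 703 and 722 BDL cells. The count was 2126 without sham replicate 2, 4950 in batch 1 alone, 2100 with equal cell numbers and 2474 at a mean CPM of at least 20.

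**Figure D2:**
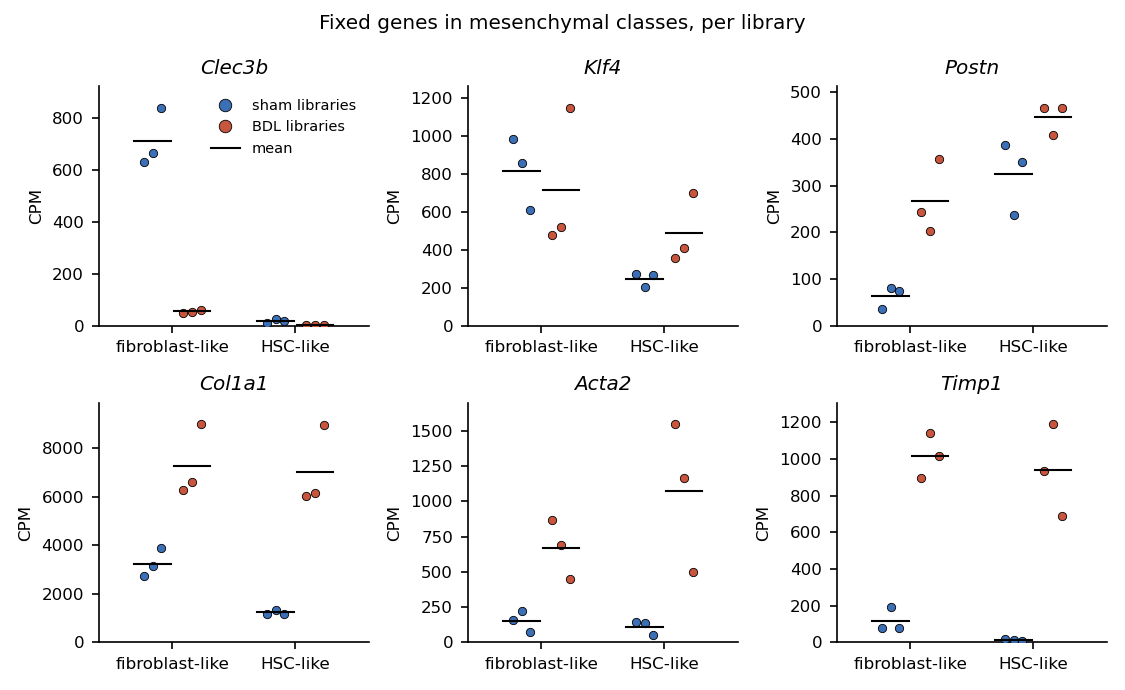
CPM of Clec3b, Klf4, Postn, Col1a1, Acta2 and Timp1 in fibroblast-like and HSC-like cells, with 1 point per library and a bar at the group mean for sham and BDL. Postn goes from a mean of 64.2 to 268 CPM in fibroblast-like cells, and Klf4 from 248 to 489 CPM in HSC-like cells.

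Klf4 and Postn responded differently in the 2 mesenchymal classes. The response of Postn was higher in fibroblast-like than in HSC-like cells by 1.54 ± 0.30 on the log2 scale (edgeR interaction, n = 3 libraries per group, adjusted p = 0.00344; 1.02 without sham replicate 1). The response of Klf4 was lower in fibroblast-like cells, by -1.26 ± 0.16 (adjusted p = 1.43e-04; -1.18 and not called without the block). Collagens and Timp1 also responded less in fibroblast-like cells, from a higher sham level: Col1a1 differed by -1.32 ± 0.13, Col1a2 by -1.22 ± 0.10 and Timp1 by -2.98 ± 0.35 (-1.42 with doublets kept). In batch 1 alone Postn differed by 1.36 and Klf4 by -1.37. In all 1486 of 13998 genes differed, 573 with the higher response in fibroblast-like cells and 913 with the lower. Of 36 matrix genes 18 were lower and 2 higher (25 and 3 adjusted over the list alone), among them Thbs1 (-1.92 ± 0.11), Fmod (-2.53 ± 0.16) and Mfap2 (-2.28 ± 0.15). Of 27 chemokine and cytokine genes 10 were lower and 0 higher (13 and 2 adjusted over the list alone), among them Ccl7 (-2.67 ± 0.17) and Cxcl2 (-2.88 ± 0.24; -1.81 with doublets kept). Of 17 contractile genes 8 were lower and 1 higher (11 and 2 adjusted over the list alone), among them Myh11 (-1.75 ± 0.24; -0.84 and not called with doublets kept). Of 26 dissociation and immediate-early genes 14 were lower and 1 higher (17 and 2 adjusted over the list alone), among them Socs3 (-1.32 ± 0.10) and Cebpb (-1.04 ± 0.12). The count was 971 without BDL replicate 2, 932 with doublets kept and 341 without the block, where the fit ignores that both classes come from the same mice, and 1844 in batch 1 alone. Of the genes named here, Thbs1, Cxcl2 (-2.92), Myh11 (-1.74), Socs3 and Cebpb were also not called without the block.

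Within BDL, fibroblast-like cells held more Klf4 and less Postn than HSC-like cells of the same mice. Klf4 was 717 ± 376 against 489 ± 183 CPM (SD, n = 3; log2 0.62 ± 0.07, edgeR adjusted p = 3.89e-04), higher in 3 of 3 libraries. Postn was 268 ± 79.5 against 447 ± 33.2 CPM (-0.65 ± 0.11, adjusted p = 0.00277), higher in 0 of 3, and not called with doublets kept (-0.46). Both calls, and 3359 of 14862 in all (1857 higher, 1502 lower in fibroblast-like cells), used library as a block; without it 661 genes were called, not Klf4 (0.68) nor Postn (-0.61). Marker genes of the classes are left out here. Of 36 matrix genes 18 were higher and 5 lower in fibroblast-like cells (19 and 5 adjusted over the list alone), with Fmod at 1.64 ± 0.06, Eln, which encodes elastin, at 1.39 ± 0.09 and Loxl2 at -0.61 ± 0.05. Of 17 matrix degradation genes 8 were higher and 0 lower (10 and 2 adjusted over the list alone), with the stromelysin Mmp3 at 3.41 ± 0.26. That list was not left out of the sub-clustering by which the classes were drawn. Of 20 TGF-beta response genes 8 were higher and 4 lower (8 and 5 adjusted over the list alone), with Itgbl1 at 2.31 ± 0.09. Contractile genes were lower, 9 of 17, with 2 higher (9 and 3 adjusted over the list alone), Csrp1 at -0.79 ± 0.06 and Tpm1 at -0.52 ± 0.05, the last not called without the block. Proliferation genes were lower, 22 of 24 with 0 higher (23 and 0 adjusted over the list alone), with Top2a at -1.43 ± 0.14 (-0.69 and not called with doublets kept). In batch 1 alone Klf4 was at 0.51 and Postn at -0.83, with 4798 genes called. The count was 1605 without BDL replicate 2 and 1784 with doublets kept.

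Among fibroblast-like cells of BDL livers, the Clec3b/Pi16-type held more Postn, at 717 ± 348 against 217 ± 41.3 CPM in the other cells (SD, n = 3; log2 1.58 ± 0.13, edgeR adjusted p = 4.85e-06), higher in 3 of 3 libraries. Klf4 was 941 ± 431 against 665 ± 350 (0.47 ± 0.08, adjusted p = 0.00177) and Tgfb1 80.8 ± 7.34 against 128 ± 20.8 (-0.72 ± 0.11). Clec3b, a naming marker of the type, was 208 ± 121 against 43.2 ± 12.1. Most BDL cells of the type were not named by Clec3b. Sub-cluster 8 of batch 1 was named by Pi16, Mfap5 and Cd55, and sub-cluster 7 of batch 2 by these, Igfbp6 and Ly6a. Sub-cluster 2 of batch 2 (419 BDL cells), with Clec3b among its leading genes, counts among the other cells. In all 2804 of 13402 genes differed, 1386 higher and 1418 lower in the Clec3b/Pi16-type. Of 36 matrix genes 16 were higher and 9 lower, with the same counts adjusted over the list alone, with Col12a1 at 4.28 ± 0.10, fibronectin (Fn1) at 1.38 ± 0.08 and Tnc at -2.47 ± 0.11. Of 17 contractile genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone), with Csrp1 at 1.99 ± 0.10. Of 21 TGF-beta response genes 5 were higher and 10 lower, with the same counts adjusted over the list alone, with the activin chain Inhba at 2.89 ± 0.11 and Tgfb3 at -1.27 ± 0.13. Proliferation genes were lower, 11 of 22 with 0 higher (14 and 0 adjusted over the list alone), with Ube2c at -2.31 ± 0.31. Of 26 dissociation and immediate-early genes 6 were higher and 4 lower (8 and 4 adjusted over the list alone), with Mt1 at -1.36 ± 0.11. These values changed at sub-clustering resolution 1, where BDL replicate 2 had 8 Clec3b/Pi16-type cells, under the minimum of 10, so that 2 libraries were compared: 392 genes differed (1759 without BDL replicate 2 as drawn here), Postn stayed called (1.42), Klf4 (0.73), Csrp1 (0.68), Inhba (0.64), Fn1 (0.34), Tgfb3 (-0.95) and Ube2c (-1.46) were not, Col12a1 was at 1.92, Tgfb1 at -1.32, and Acta2, Cald1, Col1a1 and Col1a2 changed sign (-0.35, -0.38, -0.31 and -0.078). Without the block 1190 genes differed, and in batch 1 alone 2704, with Postn at 1.33 and Klf4 at 0.51.

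Between cells named Clec3b/Pi16-type in each group, BDL against sham, Postn rose from 64.7 ± 27.6 to 717 ± 348 CPM (SD, n = 3 each; log2 3.48 ± 0.38, edgeR adjusted p = 1.86e-05), Acta2 rose by 3.81 ± 0.35 and Col1a1 by 1.71 ± 0.25, and Clec3b fell by 1.81. Klf4 was at 838 ± 189 and 941 ± 431 CPM (0.16 ± 0.28, adjusted p = 0.689). Of 10024 genes 3535 changed, 1803 up and 1732 down. H19, an imprinted non-coding RNA, and Cacna1b had 0 sham UMIs and were at least 333-fold and 64.5-fold higher. Cyp26a1, which degrades retinoic acid, had 1 (ratio of counts 658, 95% interval 118 to 26035). Igfbp2 rose by 10.12 ± 0.42, Ctla2a by 8.89 ± 0.36 and Col11a1 by 8.70 ± 0.59 on the log2 scale. Lrat (-5.41 ± 0.39), Gria1 (-5.40 ± 0.39), Ano1 (-4.66 ± 0.42), Inmt (-4.62 ± 0.32) and Fbln5, an elastic fibre protein (-4.61 ± 0.22), were among the largest falls. Lrat, which stores vitamin A, is a marker of HSC.

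Of 36 matrix genes in Clec3b/Pi16-type cells 21 rose and 5 fell (22 and 7 adjusted over the list alone), with Col12a1 at 5.37 ± 0.39 and Col8a1 at 3.06 ± 0.26. Of 17 contractile genes 14 rose and 1 fell, with the same counts adjusted over the list alone, with Csrp1 at 2.16 ± 0.18. Of 20 TGF-beta response genes 7 rose and 8 fell (7 and 9 adjusted over the list alone), with Inhba at 4.83 ± 0.28 and Bambi at -2.48 ± 0.18. Of 18 interferon response genes 14 fell and 0 rose, with the same counts adjusted over the list alone, with Ifit3 at -1.67 ± 0.34. The sums rest on 130, 138 and 50 sham and 142, 105 and 98 BDL cells, and the sub-clusters behind them differ by group (1 of 315 sham and 23 BDL cells, 1 of 3 sham and 224 BDL cells, and 1 of 98 cells in batch 2). The first was named by Clec3b, Igfbp6 and Ly6a, the second by Pi16, Mfap5 and Cd55, so in batch 1 most sham and most BDL cells were named by different markers, and these values do not tell a change within one kind of cell from a difference between 2 kinds. At sub-clustering resolution 1, where 1 sub-cluster of 229 sham cells and 1 of 5 sham and 229 BDL cells lost the name, and with 18, 34 and 11 sham and 15 and 131 BDL cells, 70 genes were called. BDL replicate 2 had 8 cells there, under the minimum of 10, and was not in that fit (2844 genes without it as drawn here). Postn (2.01), Ltbp2 (3.72) and Fbln5 (-2.32) stayed called. Acta2 (3.60), Col1a1 (0.79), Clec3b (-1.59), Col12a1 (4.39), Col8a1 (1.82), Csrp1 (1.43) and Bambi were not called there, and Inhba has no value there. In batch 1 alone the count was 4285, with Postn at 3.04 and Klf4 at -0.26.

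Cholangiocyte-like cells, the lining of the bile ducts, had the most changed genes of the classes tested: 9045 of 17024, 4516 up and 4529 down (edgeR, n = 3 each). The sums rest on 3050 sham and 6420 BDL cells, against 324 and 4269 in fibroblast-like cells. In simulated data 26.9% of genes changed 1.5-fold were called here, against 8.96% in fibroblast-like sums. Counts of changed genes therefore do not rank the classes by size of response. Klf4 fell from 178 ± 13.3 to 102 ± 17.8 CPM (SD; log2 -0.80 ± 0.13, adjusted p = 0.00144). The largest rises were of Csf3, the granulocyte growth factor (log2 6.91 ± 0.57), Wfdc18 (6.74 ± 0.47), Ccl2, the monocyte chemokine (6.29 ± 0.37, from 20.3 ± 9.29 to 1576 ± 112 CPM), the interleukin-1 antagonist Il1rn (6.16 ± 0.37), Cxcl5, a neutrophil chemokine (6.02 ± 0.37), and Mgp (5.56 ± 0.60), a mesenchymal gene at 1.53% of its level in fibroblast-like cells in BDL, with Col1a1 at 1.39%, Col3a1 at 1.83%, Timp1 at 5.47% and Sparc at 9.21%. The largest falls were of Msmp (-10.73 ± 0.44), Pigr, which carries IgA into bile (-7.59 ± 0.43), Atoh8 (-5.75 ± 0.21), Vtn (-5.25 ± 0.29), Dbp, a clock output gene (-4.86 ± 0.31), and Rbp4 (-4.63 ± 0.32). At clustering resolution 2 Msmp was at -6.19, Vtn at -2.43 and Rbp4 at -2.08, all still called.

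Of 24 proliferation genes in cholangiocyte-like cells 23 rose and 0 fell, with the same counts adjusted over the list alone, with Mki67 at 4.09 ± 0.19 and Top2a at 3.75 ± 0.21 (2.70 and 2.31 at resolution 2; camera adjusted p = 1.66e-10; adjusted p = 0.448 with an estimated correlation). Of 26 chemokine and cytokine genes 22 rose and 0 fell (24 and 0 adjusted over the list alone), with Csf1 at 2.30 ± 0.15 (camera adjusted p = 1.55e-08; adjusted p = 0.448 with an estimated correlation). Of 17 inflammatory monocyte genes 15 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 1.17e-06; adjusted p = 0.448 with an estimated correlation), and in BDL Lyz2 was at 1.96%, Il1b at 2.06%, Ccl3 at 2.15% and Cxcl2 at 19.9% of their level in monocyte/macrophage-like cells. Of 25 ductular reaction genes 15 rose and 6 fell (15 and 7 adjusted over the list alone), with the integrin Itgb6 at 2.09 ± 0.09 and Krt7 at 2.47 ± 0.12 (camera adjusted p = 0.0221; adjusted p = 0.448 with an estimated correlation). Of 15 bile acid and ductal transport genes 5 rose and 8 fell, with the same counts adjusted over the list alone. The chloride channel Cftr rose (1.43 ± 0.12), and Slc5a1 (-1.40 ± 0.10), Abcb1a (-2.91 ± 0.20) and Nr0b2, a repressor induced by FXR (-3.18 ± 0.28; -1.54 at resolution 2), fell, with a camera adjusted p of 0.634. In the KLF family 10 of 12 genes fell and 0 rose, with the same counts adjusted over the list alone, with Klf15 at -4.23 ± 0.27 and Klf9 at -2.52 ± 0.11 (camera adjusted p = 5.31e-04; adjusted p = 0.448 with an estimated correlation). Of 26 dissociation and immediate-early genes 16 fell and 3 rose, with the same counts adjusted over the list alone, with Jun at -1.53 ± 0.15 and Hspb1 at 1.31 ± 0.15 (camera adjusted p = 0.0180; adjusted p = 0.448 with an estimated correlation). Mesenchymal genes were seen here too, with Col1a1 at 2.21 ± 0.620 CPM in sham and 92.5 ± 34.9 in BDL. Sham and BDL cells lay in different clusters (3030 sham and 15 BDL cells in 1, 2 sham and 2987 BDL cells in another), and the count was 4350 at a mean CPM of at least 20 and 10818 in batch 1 alone, with Klf4 at -0.91.

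In endothelial-like cells, Dnase1l3 and other LSEC genes fell and chemokine genes rose. 4805 of 14695 genes changed, 2586 up and 2219 down (edgeR, n = 3 each). Dnase1l3, a secreted DNase, went from 1628 ± 353 to 164 ± 38.6 CPM (SD; log2 -3.31 ± 0.24, adjusted p = 1.52e-04), and Clec4g from 1320 ± 207 to 350 ± 61.1. Pla2r1 (-3.55 ± 0.23), Enpep (-3.51 ± 0.24), Aass (-3.42 ± 0.35), Dbp (-3.37 ± 0.21) and Gpr155 (-3.10 ± 0.26) were the other largest falls. The largest rises were of Wfdc18 (6.21 ± 0.87; in BDL at 3.54% of its level in cholangiocyte-like cells, with Spp1 at 2.5%, Lcn2 at 5.46% and Clu at 5.57%), Csf3 (6.02 ± 0.59), AA467197 (5.29 ± 0.31), Col1a1 (4.99 ± 0.24; in BDL at 1.94% of its level in fibroblast-like cells), H19 (4.72 ± 0.52) and Olr1, a receptor for oxidised LDL (4.54 ± 0.51). Klf4 was 1032 ± 209 in sham and 846 ± 95.8 in BDL (-0.29 ± 0.17, adjusted p = 0.241).

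Of 21 LSEC genes 15 fell and 2 rose in endothelial-like cells, with the same counts adjusted over the list alone, with Fcgr2b at -2.06 ± 0.22 and Il1a at -1.60 ± 0.12 (camera adjusted p = 5.36e-06; adjusted p = 0.432 with an estimated correlation). Of 22 capillary and vascular endothelium genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), with the apelin receptor Aplnr at 4.72 ± 0.40 and the growth factor Pgf at 4.37 ± 0.38 (camera adjusted p = 9.22e-04; adjusted p = 0.432 with an estimated correlation). Cd34 was at 1.88 ± 0.16, but at 0.32 and not called with at least 800 genes and 1500 UMIs, and Ly6c1, whose reads are hard to tell from those of near-identical genes, went from 2.23 to -0.80 there. Of 24 chemokine and cytokine genes 19 rose and 2 fell (20 and 2 adjusted over the list alone), with Il6 at 4.29 ± 0.33 and Ccl7 at 2.89 ± 0.29 (camera adjusted p = 3.42e-07; adjusted p = 0.231 with an estimated correlation). Of 17 inflammatory monocyte genes 15 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.04e-08; adjusted p = 0.407 with an estimated correlation), and in BDL Lyz2 was at 2.59%, Il1b at 3.17%, Ccl3 at 3.28% and Cxcl2 at 3.94% of their level in monocyte/macrophage-like cells. Of 14 basement membrane genes 8 rose and 1 fell, with the same counts adjusted over the list alone, with Col18a1, the source of endostatin, at 4.15 ± 0.18, the laminin Lamb1 at 2.79 ± 0.26 and perlecan (Hspg2) at -0.90 ± 0.15 (camera adjusted p = 1.99e-03; adjusted p = 0.432 with an estimated correlation). Different clusters hold most of the class in each group (2506 sham and 15 BDL cells in 1, 2197 and 1 in another, and 4 and 684 and 13 and 552 in 2 others). The count was 2893 without sham replicate 3, 6882 in batch 1 alone and 2773 at a mean CPM of at least 20.

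In monocyte/macrophage-like cells, Arg1, the arginase of alternatively activated macrophages, rose from 0.968 ± 1.18 to 84.9 ± 29.1 CPM (SD, n = 3 each; log2 6.13 ± 0.53, edgeR adjusted p = 4.37e-04), and Gpnmb, a lysosomal membrane protein, from 16.4 ± 5.48 to 238 ± 30.3 (3.82 ± 0.22). 3019 of 13811 genes changed, 1622 up and 1397 down. Other large rises were of the neutrophil and monocyte alarmins S100a8 (3 sham UMIs; ratio of counts 168, 95% interval 57.5 to 816) and S100a9 (6.66 ± 1.72; 4.38 without BDL replicate 2), Syngr1 (4.92 ± 0.29), and the mesenchymal genes Mgp (5.30 ± 0.57) and Col1a1 (4.37 ± 0.35), in BDL at 1.97% and 1.71% of their level in fibroblast-like cells. The calls of S100a8 and S100a9 ended without any of the sham libraries (7.07 to 8.20 and 6.32 to 7.49). In BDL replicates 1, 2 and 3, S100a8 was at 27.7, 188 and 19.2 CPM, by far the highest in replicate 2. S100a8 and S100a9 are naming markers of neutrophil-like cells, as is Mmp9, which fell here. Neutrophil-like cells went from 0.0760% to 2.64% of captured cells. S100a9 rose in fibroblast-like sums too (ratio of counts 29.7, 95% interval 8.21 to 246). How much of these counts came from neutrophils was not separated. The largest falls were of Retnla (-7.94 ± 1.38), Cxcl13, a B cell chemokine (-7.85 ± 0.70), Pla2g2d (-7.41 ± 0.37), H2-M2 (-5.72 ± 0.39), Dnase1l3 (-4.54 ± 0.37) and Mmp9 (-4.53 ± 0.59). Retnla was at 3.61, 343 and 177 CPM in sham replicates 1, 2 and 3, and at 0.318, 1.70 and 0 CPM in those of BDL. Klf4 was at -0.22 ± 0.13 (adjusted p = 0.256).

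Of 17 lipid-associated macrophage genes 11 rose and 1 fell in monocyte/macrophage-like cells (14 and 2 adjusted over the list alone), with Trem2 at 2.03 ± 0.17, the protease Ctsd at 1.66 ± 0.18 and Itgax at -1.49 ± 0.13 (camera adjusted p = 1.06e-04; adjusted p = 0.143 with an estimated correlation). Of 17 inflammatory monocyte genes 10 rose and 0 fell (10 and 1 adjusted over the list alone), with Cxcl2 at 1.94 ± 0.19 and Nlrp3 at 1.39 ± 0.22 (camera adjusted p = 1.72e-03; adjusted p = 0.337 with an estimated correlation). Of 17 hypoxia and glycolysis genes 7 rose and 0 fell (8 and 0 adjusted over the list alone), with Pkm at 1.25 ± 0.15 (camera adjusted p = 0.0164; adjusted p = 0.313 with an estimated correlation). Of 15 Kupffer identity genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), with Nr1h3, the oxysterol receptor, at -2.00 ± 0.12 and Timd4 at -4.71 ± 0.64 (camera adjusted p = 1.23e-05; adjusted p = 0.336 with an estimated correlation). That list holds Cdh5 (-2.97 ± 0.38), also a marker of endothelial cells, and LSEC genes such as Clec4g (-4.30) and Stab2 (-3.97) fell in this class too. Of 13 MHC class II and antigen presentation genes 2 fell and 0 rose, with the same counts adjusted over the list alone: Ciita, the class II activator (-1.25 ± 0.18), and B2m (-0.69 ± 0.16), with a camera adjusted p of 0.0115 and an adjusted p of 0.519 with an estimated correlation. Neither call held with at least 800 genes and 1500 UMIs (-0.68 and -0.57), and that of B2m ended without sham replicate 1 (-0.69), 2 (-0.65) or 3 (-0.61) or BDL replicate 2 (-0.65), and with doublets kept (-0.55). The count was 1440 without sham replicate 2, 4755 in batch 1 alone, 5002 with batch as a covariate, 988 with at least 800 genes and 1500 UMIs and 1486 with equal cell numbers. Of the clusters of the class, 1 held 358 sham and 25 BDL cells and another 84 and 3181. BDL replicate 3 lay almost apart, in a cluster in which it made up 96.8% of the BDL cells.

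In Kupffer-like cells, Gpnmb rose from 8.71 ± 5.21 to 251 ± 11.8 CPM (SD, n = 3 each; log2 4.85 ± 0.30, edgeR adjusted p = 2.75e-05), Emp1 rose by 4.53 ± 0.45 and Apoe by 1.99 ± 0.29, and Cxcl13 fell by 5.00. 1982 of 8348 genes changed, 1079 up and 903 down. Mesenchymal genes were among the largest rises, Timp1 (4.80 ± 0.78), Col1a1 (4.40 ± 0.49), Mgp (4.30 ± 0.60) and Col3a1 (4.30 ± 0.58), in BDL at 3.91%, 2.12%, 2.05% and 2.62% of their level in fibroblast-like cells, and endothelial genes among the largest falls, Kdr (-4.77 ± 0.32), Ehd3 (-4.35 ± 0.26), Cyp4b1 (-5.05 ± 0.52) and Adgrf5 (-4.13 ± 0.28). Ces1d, which has near-identical neighbours, had 3 BDL UMIs (sham over BDL, ratio of counts 70.8, 95% interval 23.8 to 347). Klf4 was at -0.86 ± 0.25 (adjusted p = 0.0314), a call that ended without sham replicate 1 (-0.92), 2 (-0.71) or 3 (-0.96) or BDL replicate 1 (-0.61) or 2 (-0.87). Of 17 lipid-associated macrophage genes 7 rose and 0 fell (8 and 2 adjusted over the list alone), with Trem2 at 3.12 ± 0.23 (1.93 with doublets kept; camera adjusted p = 3.77e-03; adjusted p = 0.323 with an estimated correlation). Of 15 Kupffer identity genes 11 fell and 0 rose (12 and 0 adjusted over the list alone), with Cd163 at -1.88 ± 0.32 (-1.02 with doublets kept; camera adjusted p = 3.42e-05; adjusted p = 0.450 with an estimated correlation). Of 11 inflammatory monocyte genes 7 rose and 0 fell, with the same counts adjusted over the list alone, with Cxcl2 at 1.96 ± 0.24 (camera adjusted p = 4.36e-04; adjusted p = 0.215 with an estimated correlation). Of 19 chemokine and cytokine genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with Il1rn at 1.78 ± 0.30 (camera adjusted p = 1.07e-03; adjusted p = 0.362 with an estimated correlation). Of 20 LSEC genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), with Clec4g at -3.77 ± 0.29 (camera adjusted p = 3.63e-07; adjusted p = 0.215 with an estimated correlation). The count was 1075 without BDL replicate 2 and 1221 by the DESeq2 Wald test, and 2230 in batch 1 alone.

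**Figure D3:**
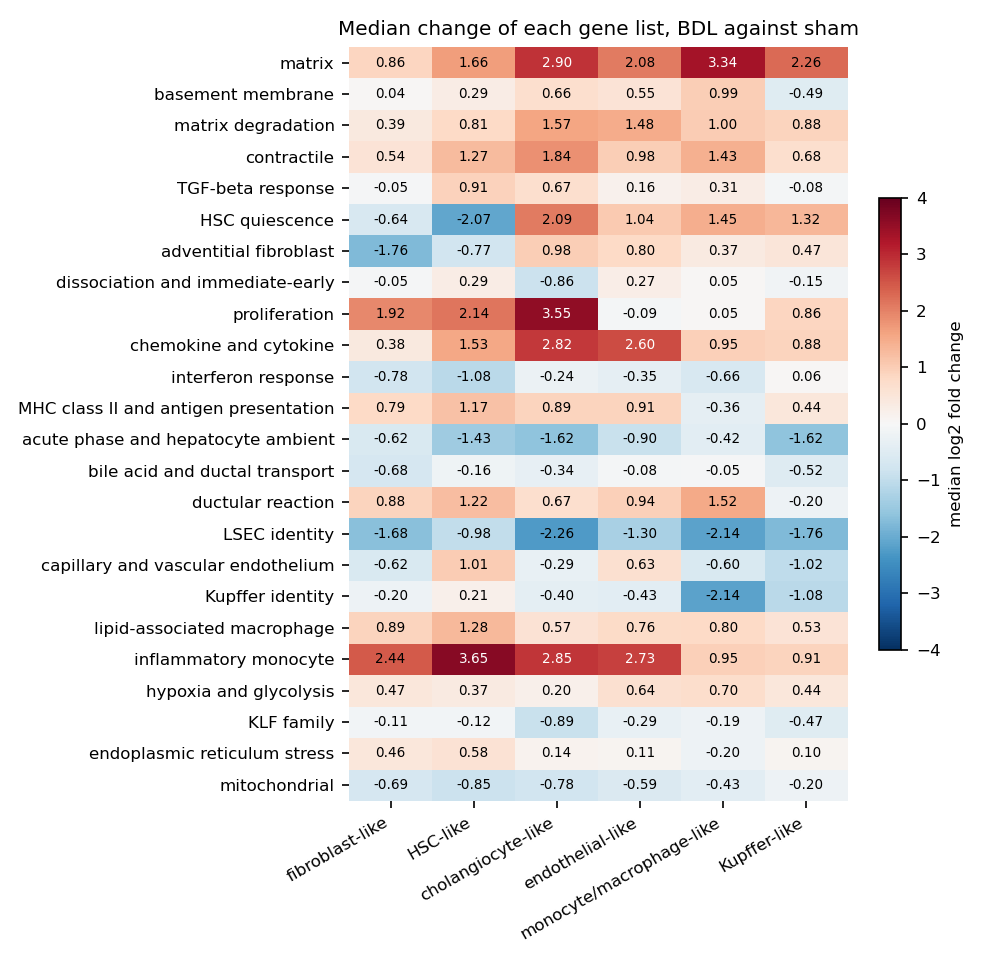
Median log2 fold change, BDL against sham, of the tested members of each of 24 gene lists in 6 cell classes, on a colour scale from blue (lower in BDL) to red (higher). Proliferation genes have a median of 3.55 in cholangiocyte-like cells, and LSEC genes one of -1.30 in endothelial-like cells.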

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

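Of the tests in this part, those of doublets and of a batch difference shared by all classes were set out before their results were seen, and all others, the splits of the libraries included, were chosen after. The test of the difference between 2 classes (an interaction term) singled out the genes below.

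The response to BDL differed between fibroblast-like and HSC-like cells in 1486 genes by edgeR (3 libraries per group). Of the fixed genes, the response in fibroblast-like minus HSC-like cells was 1.54 for Postn and 0.52 for Pdgfrb, and -1.26 for Klf4, -1.21 for Clec3b, -1.32 for Col1a1, -1.22 for Col1a2, -0.85 for Col3a1, -1.03 for Acta2 and -2.98 for Timp1 on the log2 scale. The call of Clec3b, which HSC-like cells hold at a low level, ended without the block. The highest values were those of Mapt (4.94), Colec10 (4.93), Ank3 (4.51), Rgs5 (4.40), Reln (4.14) and Fcna (3.90), and the lowest those of Il6 (-8.01), Tenm3 (-7.72), Mmp3 (-5.48), Ace (-5.00), Sfrp1 (-4.93) and Ptgs2 (-4.84). Il6, Tenm3, Mmp3 and Ace had 0 to 3 UMIs in HSC-like sham cells, and Mapt and Colec10 in fibroblast-like sham cells, so these fitted values are no bounds. The response was lower in fibroblast-like cells for 18 of 36 matrix genes and higher for 2 (Thbs1 -1.92, Fmod -2.53, Mfap2 -2.28), lower for 10 of 27 chemokine and cytokine genes and higher for 0 (Ccl7 -2.67, Cxcl2 -2.88, Cxcl1 -1.84), lower for 8 of 17 contractile genes and higher for 1 (Myh11 -1.75, Cnn2 -0.72, Tagln -0.97, Tpm2 -0.89) and lower for 14 of 26 dissociation and immediate-early genes and higher for 1 (Socs3 -1.32, Cebpb -1.04, Nfkbia -1.03, Mt2 -2.04, whose reads are hard to tell from those of a near-identical gene). The calls of Klf4 (-1.18), Acta2, Pdgfrb, Colec10, Tenm3, Thbs1, Cxcl2, Cxcl1, Myh11, Cnn2, Tagln, Tpm2, Socs3, Cebpb and Nfkbia also ended without the block.

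Klf4 responded less in fibroblast-like than in HSC-like cells. A dissociation response that differs between the classes would move Klf4 with the other immediate-early genes. Their median difference was -0.56 (quartiles -0.69 and -0.18), and Klf4 lay -0.69 from it, below the lower quartile. However, 3 of 26 genes lay below Klf4 and 14 of the 26 were called lower themselves. Klf4 thus lies within the spread of the list, so this test does not decide on a dissociation response. BDL replicate 3 alone is argued against by the value without it, -1.37. Free RNA holding Klf4 goes with the level of Klf4 in T/NK-like and B cell-like sham cells, a median of 65.0% of that in HSC-like cells (24.4% to 97.1%); what these cells make themselves was not separated. An estimate made after that value was seen used the median over 7 sinusoidal genes in each library, which was 4.21% to 5.78% of the whole-library level in HSC-like sham cells. Of these genes 6 lay at 1.14% to 7.57%, and Rspo3 lay at 127% to 255%. By those medians free RNA would give 25.1 to 40.9 CPM of Klf4 against 224 to 284 measured (both before TMM), a median of 9.25% (8.93% to 18.2%). That estimate assumes that free RNA has the profile of the whole library, which was not measured, so it excludes nothing. A dissociation response, free RNA, a difference in which cells the classes hold and a difference in Klf4 regulation between the 2 classes all stay open.

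Matrix genes rose and LSEC genes fell in classes that are not their main source. Free RNA from mesenchymal cells goes with the collagens: in other classes, Col1a1, Col1a2, Dcn and Lum relative to Col3a1 lay a median of 0.387 (log2) from mesenchymal cells of the same library. Free RNA from sinusoidal cells goes with 7 LSEC genes: over the 40 pairs of gene and class that were called, their change lay a median of 0.824 from that of whole libraries (-4.91; median absolute deviation 0.511). Over all 44 pairs tested, called or not, of which 43 fell, this was 0.865 (median absolute deviation 0.549). Doublets with mesenchymal cells are argued against as the main cause by the percent of a class's collagen UMIs that lay in cells with over 50 of them, a median of 0.116% over 10 classes and 3.38% over these classes together. It was at most 3.74% in 8 classes, but 51.2% in hepatocyte-like and 46.6% in mesothelial-like cells, where doublets stay open. Timp1 was first tested over 3 classes together (mean excess over the collagens 1.59 ± 0.682, undecided) and then by class. The excess was 1.99 ± 0.647 (SD, n = 3) in cholangiocyte-like and 1.95 ± 0.394 in endothelial-like cells. That argues against free RNA with the Timp1 to collagen ratio of mesenchymal cells as its whole cause there. In monocyte/macrophage-like cells it was 0.839 ± 0.0893, and the cause cannot be told apart since that excess is small. Free RNA with more Timp1 stays open. In BDL, T/NK-like cells held Timp1 at 4.13% and Col1a1 at 2.05% of their level in fibroblast-like cells. In dendritic-like cells these were 3.51% and 1.62%, and in B cell-like cells 1.90% and 2.79%.

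BDL replicate 3 stood apart from BDL replicates 1 and 2. Its shift in fibroblast-like cells had a median size of 0.267 against 0.0829 between the other 2, and in HSC-like cells 0.304 against 0.0983. A batch difference shared by all classes goes with a correlation of the shift between classes of 0.720 (0.513 to 0.901 over 15 pairs of classes), against 0.333 for the difference of replicates 1 and 2. Its batch holds no other library, so a batch and a mouse that differs cannot be told apart. A gene reference in batch 2 that lacks genes is argued against by 0 genes at 20 or more CPM in BDL replicates 1 and 2 and at 0 UMIs in BDL replicate 3, a test narrowed after this value was seen. How reads of near-identical copies were counted was not tested.

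With 3 libraries per group there are 10 splits, and with 3 BDL libraries 4 ways to swap the 2 kinds of cell, too few for a share under 0.05. Every other split also mixes sham with BDL libraries, or the 2 kinds of cell, within a group. A real difference then widens the spread within groups, so few genes called in those splits are no measure of chance. The real split gave 3477 genes in fibroblast-like, 3806 in HSC-like, 9045 in cholangiocyte-like, 4805 in endothelial-like, 3019 in monocyte/macrophage-like, 1982 in Kupffer-like, 1627 in smooth muscle/pericyte-like, 2770 in hepatocyte-like, 1778 in dendritic-like, 234 in T/NK-like, 30 in B cell-like and 3535 in Clec3b/Pi16-type cells, 1486 for the difference in response, 3359 within BDL and 2804 between subtypes, with 0 in the highest other split of each. In mesothelial-like cells it gave 464 and the highest other 1. Gene lists called by camera were 10 in fibroblast-like cells (highest other split 9), 15 in HSC-like (10), 17 in cholangiocyte-like (13), 13 in endothelial-like (13, so that 2 splits gave as many), 16 in monocyte/macrophage-like (11) and 11 in Kupffer-like cells (10).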

How the results depend on the processing

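All alternatives here were chosen before the data were examined. Of 4855 alternatives for named genes, 4647 kept direction and call, 130 lost the call, 47 gained it, 24 moved and 7 reversed; of 2846 that left out 1 library, 2684 kept both, 128 lost the call, 18 gained it and 16 moved. The cause was not tested, except that a higher CPM minimum tests fewer genes and equal cell numbers use fewer cells. Counts of genes at a mean CPM of at least 20 were 2096 (fibroblast-like), 2474 (HSC-like), 4350 (cholangiocyte-like), 2773 (endothelial-like), 1060 (dendritic-like), 90 (T/NK-like) and 56 (B cell-like). With equal cell numbers they were 1811 (fibroblast-like), 2100 (HSC-like), 1486 (monocyte/macrophage-like), 655 (smooth muscle/pericyte-like), 234 (mesothelial-like), 1070 (hepatocyte-like), 637 (dendritic-like) and 24 (T/NK-like). With batch as a covariate they were 5607 (fibroblast-like), 5002 (monocyte/macrophage-like), 790 (mesothelial-like), 3025 (dendritic-like) and 623 (T/NK-like). Without a filter they were 882 (mesothelial-like), 2830 (dendritic-like), 878 (T/NK-like) and 240 (B cell-like). With doublets kept they were 769 (mesothelial-like), 723 (T/NK-like), 395 (B cell-like), 932 (difference in response) and 1784 (within BDL). The DESeq2 Wald test gave 1221 (Kupffer-like) and 298 (mesothelial-like). At least 800 genes and 1500 UMIs gave 988 (monocyte/macrophage-like), a mitochondrial share of at most 10% gave 509 and clustering resolution 2 gave 487 (hepatocyte-like, both without BDL replicate 1, which fell under 10 cells). Without the block 341 genes differed in response, 661 within BDL and 1190 between subtypes, and at sub-clustering resolution 1 the counts were 392 between subtypes and 70 in Clec3b/Pi16-type cells, both without BDL replicate 2, which fell to 8 such cells. With doublets kept, the share of collagen UMIs in BDL was 47.9% in fibroblast-like and 22.6% in HSC-like cells.

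Camera with an estimated correlation called 0 lists in each of the 12 classes, with 3 (fibroblast-like), 5 (HSC-like), 1 (cholangiocyte-like), 2 (endothelial-like), 2 (monocyte/macrophage-like), 3 (Kupffer-like), 4 (smooth muscle/pericyte-like), 3 (mesothelial-like), 4 (hepatocyte-like), 7 (dendritic-like), 1 (T/NK-like) and 3 (B cell-like) at an unadjusted p under 0.05. Reversed were Ly6c1 in endothelial-like cells with doublets kept (-0.16), at a mitochondrial share of at most 10% (-0.52) and with at least 800 genes and 1500 UMIs (-0.80), and between subtypes at sub-clustering resolution 1 Acta2 (-0.35), Cald1 (-0.38), Col1a1 (-0.31) and Col1a2 (-0.078). The share of smooth muscle/pericyte-like cells reversed at a mitochondrial share of at most 10% (-0.0301 points) and with at least 800 genes and 1500 UMIs (-0.00808), and that of unnamed cells with doublets kept (1.18) and at a mitochondrial share of at most 10% (1.31). The scaling by DESeq2 size factors moved the median of all genes by -0.0624 (hepatocyte-like) or less in size; without a filter it moved by 0.12 (fibroblast-like), 0.13 (HSC-like), -0.12 (endothelial-like) and -0.20 (B cell-like), and at a mean CPM of at least 20 by -0.11 (HSC-like), -0.10 (fibroblast-like) and -0.10 (monocyte/macrophage-like).

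Leaving out 1 library at a time, counts of genes ranged from 1929 (without sham replicate 2) to 5032 (without BDL replicate 3) in fibroblast-like, 2126 to 4950 (the same libraries) in HSC-like, 2893 (without sham replicate 3) to 6882 in endothelial-like, 1440 to 4755 in monocyte/macrophage-like, 1075 (without BDL replicate 2) to 2230 in Kupffer-like, 889 to 2304 in smooth muscle/pericyte-like, 173 (without BDL replicate 1) to 873 in mesothelial-like, 666 to 3278 in dendritic-like, 7 (without BDL replicate 2) to 673 in T/NK-like and 23 to 55 in B cell-like cells. They ranged from 971 to 1844 for the difference in response, 1605 to 4798 within BDL and 1759 to 2704 between subtypes (without BDL replicates 2 and 3). Lists ranged from 10 to 17 in monocyte/macrophage-like, 7 to 12 in mesothelial-like and 5 to 10 in B cell-like cells, and differences in share from -0.573 to 2.29 points for cholangiocyte-like and -0.235 to 0.280 for smooth muscle/pericyte-like cells. With at least 800 genes and 1500 UMIs cholangiocyte-like cells could not be tested, since 2980 sham cells of the class were then in unnamed clusters (55 were removed), hepatocyte-like cells have no value there, and neutrophil-like cells were too few in sham to test.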

Other observations

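The test of clock genes in this part was chosen after the fall of Dbp was seen.

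In smooth muscle/pericyte-like cells, which wrap vessels, Acta2 did not pass the test (log2 -0.40 ± 0.28, SE, n = 3 per group; edgeR adjusted p = 0.362), and matrix genes rose. Rgs16, a brake on G protein signalling, went from 15.8 ± 9.51 to 491 ± 42.1 CPM (SD; log2 4.90 ± 0.29), Gpx3 rose by 4.79 ± 0.38 and Serpina3n by 5.05 ± 0.47, and Tcap fell from 796 ± 229 to 18.1 ± 17.5 CPM (-5.34 ± 0.46). Different sub-clusters hold most of the class in each group: in batch 1, sub-cluster 9, led by Myh11 and Tcap, held 109 sham and 33 BDL cells, sub-cluster 11 held 56 and 17 and sub-cluster 10, led by Higd1b, held 15 and 123, and in batch 2 sub-clusters 5 and 10 held 146 and 23 BDL cells. These changes, that of Tcap among them, therefore do not tell a change within cells from a change in which cells the class holds. Postn was at 1.00 ± 0.29, a call that ended without sham replicate 1 (0.75) or 3 (0.90), without BDL replicate 2 (0.91) and at a mitochondrial share of at most 10% (0.79). Of 35 matrix genes 26 rose and 0 fell (29 and 0 adjusted over the list alone; camera adjusted p = 4.07e-12; adjusted p = 0.201 with an estimated correlation). In all 1627 of 9039 genes changed, 927 up and 700 down. In mesothelial-like cells, the covering of the liver, 464 of 6999 genes changed, 226 up and 238 down. Serpina3n, a protease inhibitor, had 0 sham UMIs and was at least 81.5-fold higher, Cxcl2 rose by 5.14 ± 0.37 and Prg4, a lubricant of serous surfaces, by 4.54 ± 0.41. Of 26 dissociation and immediate-early genes 13 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.39e-10; adjusted p = 0.233 with an estimated correlation). In hepatocyte-like cells 2770 of 7020 genes changed, 1336 up and 1434 down. Lcn2, an iron-binding acute phase protein, went from 25.4 ± 16.9 to 2632 ± 306 CPM (6.68 ± 0.54), and Cyp4a12a, a fatty acid hydroxylase, had 0 BDL UMIs and was at least 118-fold lower. Of 22 ductular reaction genes 19 rose and 0 fell there (20 and 0 adjusted over the list alone; camera adjusted p = 8.81e-10; adjusted p = 0.184 with an estimated correlation). Relative to cholangiocyte-like cells of the same library, hepatocyte-like cells held Spp1 at a mean of 9.16% in sham and 174% in BDL, Clu at 12.9% and 181%, and Lcn2 at 4.81% and 110%, and their Alb level was 33180 CPM in sham and 5204 in BDL. At a mitochondrial share of at most 10%, 61 of the 140 BDL cells and 5 of the 224 sham cells were named cholangiocyte-like instead, so these changes do not tell a change within hepatocytes from a difference in which cells the class holds.

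In dendritic-like cells, which present antigen, 1778 of 11496 genes changed (edgeR, n = 3 per group), 997 up and 781 down. Ifitm1, an interferon-induced membrane protein, went from 23.4 ± 2.83 to 788 ± 77.5 CPM (SD; log2 5.06 ± 0.17, SE), and Xlr fell from 72.2 ± 22.7 to 4.07 ± 0.926 CPM (-4.13 ± 0.30). Of 24 proliferation genes 9 fell and 0 rose (17 and 0 adjusted over the list alone; camera adjusted p = 7.46e-07; adjusted p = 0.374 with an estimated correlation). In T/NK-like cells 234 of 9621 genes changed, 126 up and 108 down, or 7 without BDL replicate 2. Mgp, a gene of mesenchymal cells, rose there by 5.69 ± 0.65, to 2.39% of its level in fibroblast-like cells, and of 21 matrix genes 16 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 1.22e-20; adjusted p = 0.443 with an estimated correlation). In B cell-like cells 30 of 2104 genes changed, 28 up and 2 down, among them the complement genes of macrophages C1qa (6.03 ± 0.57), C1qb (5.92 ± 0.61) and C1qc (6.33 ± 0.79).

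Dbp, an output gene of the circadian clock, fell in 6 of 6 classes tested. A candidate explanation is libraries taken at different circadian phases. In that case the other clock genes would move as in a phase shift, and of 66 tests 47 gave a call, of which 100% (47 of 47) went that way: Nr1d1, Nr1d2 and Per1 fell in 6 classes each and Arntl rose in 3. An effect of BDL on the clock itself would give the same, and the labels give no time of day, so the 2 cannot be told apart.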
